A study of Homo sapiens with 12 samples.

How the data were processed

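RNA sequencing libraries of A549 cells were put into 4 groups of 3 by the genotype and treatment in their titles and labels. The genotype label says LKB1-deficient for those titled con and wild type for the others, which were read as LKB1-intact from the series design. Per the submitters' processing notes, the tools used include fastp 0.18.0, Bowtie2 2.2.8, HISAT2 2.1.0, StringTie 1.3.1 and RSEM. Their roles and order, the RSEM version, the genome build and whether counting used strand are not given in the sources used here. The authors deposited 1 table of estimated counts and 1 table of FPKM values (fragments scaled by transcript length and library depth), each with 20323 genes. The deposited estimated counts are not all whole: 10.9 to 11.5% of the values of a library have a fraction. The deposited FPKM values, which are divided by length and depth, summed to 500366 to 560678 per library and were higher under AA than under PBS. A count estimator that shares reads among similar transcripts makes single members of gene families uncertain.

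Genes were identified by the Ensembl identifiers and symbols of the tables. Of the identifiers, 20301 were in the name table and 20171 in GENCODE release 29, 19769 of them protein-coding there. A symbol stood at more than 1 identifier in 475 cases. The identifier that the name table gives that symbol, or else the one with the highest total, kept it, and 488 identifiers stayed unnamed. Positions are those of the GENCODE annotation on GRCh38 and were not matched to the authors' build.

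Counts were rounded to whole numbers and filtered by group with a minimum count of 10, which left 12718 genes and 99.97% of all counts. Library totals ran from 16055534 to 20306129, and TMM factors from 0.987 to 1.033. The median standard error of a log2 change between groups was 0.0706 in deficient cells. edgeR 4.0.16 (R 4.3.3) fitted 1 quasi-likelihood model to the 12 libraries, with group as the factor and no covariate. It tested 5 comparisons: AA against PBS in each genotype, the difference between these effects, and the genotypes under PBS and under AA. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. The standard error was the log2 fold change over the square root of F. CPM values are TMM-scaled, and log2 CPM used a prior count of 2.

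Of 40 gene lists fixed before the data were examined, 36 had at least 5 tested members. They were tested two-sided with camera in limma 3.58.1 on log2 CPM with an inter-gene correlation of 0.01, and adjusted over the lists of a comparison. The estimated correlation and fry, which asks whether members move one way without comparing them with other genes, were alternatives. Genes named were fixed by a rule: STK11, the 8 largest rises and falls per comparison among called genes with a symbol, a mean log2 CPM of at least 3 and no overlap of the groups' libraries (not asked of the difference), and up to 4 members of smallest p among called members of each described list, or up to 2 of highest mean expression, as values, where none was called. All tested pyroptosis genes could be named. Some genes that the rule takes are not reported here. Described lists were pyroptosis, NRF2 targets, integrated stress response, iron handling and CREB-CRTC targets in the AA comparisons, and each list that passed.

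The alternatives were a replicate block, DESeq2 1.42.0, RLE, upper quartile or no composition factors, other filters, limma on log2 FPKM with a pseudocount of 1 or 0.1 and a minimum of 1 FPKM in 3 libraries, limma-voom, stricter thresholds, the 6 libraries of a comparison alone, and leaving out each library. The steps were tested on simulated counts for 12568 genes after filtering, of which 200 were changed in deficient cells under AA. In the comparison of AA with PBS in deficient cells, 40% of genes changed by 0.25 log2 were recovered, 84% at 0.5, 88% at 1 and 98% at 2, with 6 false calls among 161. For the difference in AA effect these shares were 24%, 74%, 80% and 96%, with 4 false calls among 141, and for the genotypes under AA 40%, 86%, 88% and 98%, with 11 among 167. In the simulated comparison of genotypes under PBS, with no gene changed, no gene was called, and in that of AA with PBS in intact cells, also with no gene changed, 3 were. The 200 simulated changes were few and evenly up and down. In the real libraries, 74.4% of genes were called under AA in deficient and 69.8% in intact cells. The simulated shares and false calls therefore need not hold for these comparisons. Replicates were compared before averaging: the chi-square per degree of freedom between libraries of a group lay between 1.99 and 4.46, above the sampling noise at 1, so no library was taken for a copy.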

Results

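Gene expression was measured by RNA sequencing in A549, an established human lung adenocarcinoma line, in cells with intact or deficient LKB1. LKB1 is the serine/threonine kinase encoded by STK11, an upstream activator of AMPK. A549 is widely described as lacking functional LKB1 through a mutation of STK11, and the labels do not say how the intact and the deficient cells were made. The genotype label of the cells taken as intact says wild type, and the series design names deficient and intact LKB1. Cells of each kind received phosphate-buffered saline (PBS) or high-dose AA, which the sample titles call vitamin C (ascorbate), and no dose or exposure time is given. Each of the 4 groups had 3 libraries. Nothing in the labels says that the 3 came from separate cultures, so the p-values measure the spread between these libraries, which may be technical. The estimated counts summed to 16055534 to 20306129 per library, and 12718 genes of 20323 passed the low-count filter. The study's title concerns a vulnerability of LKB1-deficient lung cancer cells to AA-induced pyroptosis, a lytic form of cell death carried out by gasdermins.

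STK11 (ENSG00000118046; chromosome 19, 1177558 to 1228435, plus strand, a protein-coding gene in the GRCh38 annotation of GENCODE release 29) was measured first, as a check of the labels. Its level was 24.5 ± 0.917 CPM (SD, n = 3) in LKB1-intact and 5.79 ± 0.862 CPM (SD, n = 3) in LKB1-deficient cells under PBS. Under AA the levels were 26.1 ± 2.0 and 6.64 ± 0.910 CPM (SD, n = 3 each). The difference was -2.08 on the log2 scale under PBS (SE 0.11, edgeR adjusted p = 1.48e-10) and -1.98 under AA (SE 0.104, adjusted p = 5.29e-13). All 6 deficient libraries lay below all 6 intact ones. AA itself gave log2 changes in STK11 of 0.19 (SE 0.13, adjusted p = 0.189) in deficient and 0.09 (SE 0.0883, adjusted p = 0.391) in intact cells.

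**Figure D1:**
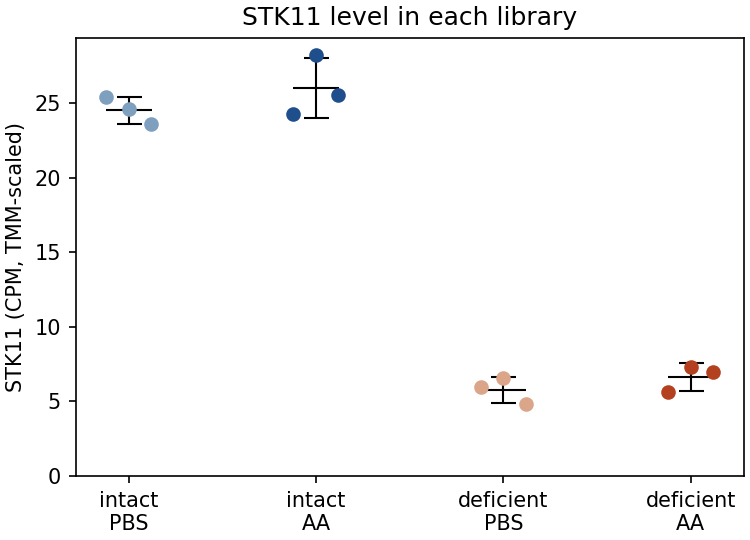
STK11 level in CPM (counts scaled to library size with TMM factors) in each of the 12 libraries, by group. Points are libraries, the wide line is the mean and the bars are 1 SD of 3 libraries. The group means were 24.5, 26.1, 5.79 and 6.64 CPM from left to right.

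The response of LKB1-deficient cells to AA was taken first. Genes of the integrated stress response, the program that ATF4 drives when amino acids run short or translation initiation is blocked, rose. Of 32 tested members, 29 rose and 3 fell, with a median log2 change of 1.33 (camera adjusted p = 6.05e-10, and adjusted p = 0.00205 with an estimated correlation). ASNS, which makes asparagine, went from 57.8 ± 5.43 to 366.5 ± 8.07 CPM (SD, n = 3), a 6.33-fold rise. PSAT1, an enzyme of serine synthesis, rose 3.00-fold (log2 SE 0.0292), and the alanyl- and seryl-tRNA synthetases AARS1 and SARS1 rose 2.64-fold and 2.82-fold.

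Genes were taken as abundant at a mean log2 CPM of at least 3 over the 12 libraries. The largest rises among them in these cells were those of ARC, a synaptic scaffold gene, and of the growth-factor-induced transcription factors EGR1 and FOS. These 3 passed that floor through their AA levels and were low under PBS. ARC rose from 0.163 ± 0.0715 to 23.2 ± 1.48 CPM, EGR1 from 0.488 ± 0.217 to 22.6 ± 0.780 CPM and FOS from 2.18 ± 0.115 to 51.1 ± 4.15 CPM (SD, n = 3 each). NR4A2 and FOSB rose 10.2-fold and 8.90-fold. The list of immediate early genes, which holds EGR1, FOS and FOSB but not ARC or NR4A2, had 17 of 23 members up and 5 down (camera adjusted p = 0.00107, and adjusted p = 0.133 with an estimated correlation). CREB-CRTC targets, which the LKB1-dependent salt-inducible kinases restrain, share FOS with this list and include NR4A2. Of 20 tested, 14 rose and 3 fell (adjusted p = 0.0266, and adjusted p = 0.117 with an estimated correlation). PTGS2, which encodes cyclooxygenase-2, rose 6.37-fold and ID1 fell (log2 -0.87). Outside the immediate early and CREB-CRTC lists, GDF15, a stress-induced cytokine, rose 10.4-fold, ABCG1, a sterol exporter, 15.3-fold and the ETS factor ETV5 7.53-fold.

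Most genes of the heat shock list fell in deficient cells. HSPA8, the constitutive HSC70 chaperone, dropped from 2640 ± 37.1 to 461.6 ± 18.6 CPM (SD, n = 3; log2 -2.52, SE 0.0266). HSP90AA1 and HSP90AB1 fell by 0.99 and 0.55 on the log2 scale, and HSPA1A, which shares reads with its near-identical copy HSPA1B and is uncertain as a single gene, by 1.66. The heat shock list had 16 of 19 members down and 2 up (camera adjusted p = 0.000199, and adjusted p = 0.117 with an estimated correlation). All 13 genes of the mitochondrial genome fell (median log2 -1.29, adjusted p = 5.32e-07, and adjusted p = 0.2 with an estimated correlation), with MT-CYB at -1.65 and MT-ND5 at -2.14. Their share of all counts was 5.20 ± 0.147% under PBS and 2.59 ± 0.0481% under AA (SD, n = 3). Cholesterol biosynthesis had 19 of 24 members down and 4 up (adjusted p = 0.000199, and adjusted p = 0.0942 with an estimated correlation). HMGCS1, early in the pathway, fell by 1.73 on the log2 scale.

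Ribosomal protein genes rose in deficient cells, 43 of 45 with none down (median log2 0.55, camera adjusted p = 6.86e-10, and adjusted p = 0.391 with an estimated correlation), led by RPL12 (0.89) and RPS2 (0.85). Nuclear genes of oxidative phosphorylation had 28 of 38 up and 2 down (median 0.34, adjusted p = 0.000199, and adjusted p = 0.396 with an estimated correlation), among them COX6A1 (0.57) and SDHB (0.49). With the trend of log2 change on transcript length removed, the ribosomal protein median was 0.19 and stayed called (adjusted p = 0.00127), and the oxidative phosphorylation median was 0.06 and its call was lost (adjusted p = 0.242). Replication-dependent histone genes had 9 of 10 up and none down (adjusted p = 0.00236, and adjusted p = 0.0942 with an estimated correlation), led by H2AC6 (log2 2.46), of a multigene family whose members can share reads. G2 and M phase genes had 22 of 30 up and 4 down (adjusted p = 0.00128, and adjusted p = 0.117 with an estimated correlation). HMMR rose by 1.24 on the log2 scale while the proliferation marker MKI67 fell by 0.84.

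The pyroptosis list did not pass in deficient cells (camera adjusted p = 0.136), with 9 of 17 tested members up and 3 down. TXNIP, a thioredoxin-binding protein that activates the NLRP3 inflammasome, rose 3.27-fold, CASP4, the caspase that senses cytosolic lipopolysaccharide, 1.89-fold, and IL18, a cytokine matured by caspase-1, 2.06-fold. GSDME, a gasdermin, rose 1.24-fold (adjusted p = 1.6e-07), and CASP1 1.21-fold (adjusted p = 0.0182). NINJ1, IL1A, PYCARD and NLRC4 rose too, the last at 0.685 ± 0.0980 CPM (SD, n = 3) under AA. DPP9 and NEK7 fell by 0.43 and 0.14 on the log2 scale. The calls of CASP1 (without deficient AA replicate 1, edgeR adjusted p = 0.094), NLRC4 (without deficient PBS replicate 3, adjusted p = 0.0655), NINJ1 (without deficient PBS replicate 1, adjusted p = 0.105, or 2, 0.0634, or deficient AA replicate 3, 0.134) and NEK7 (without deficient PBS replicate 2, adjusted p = 0.104, or deficient AA replicate 3, 0.216) were lost without those libraries. The NEK7 call was also lost with upper quartile factors (adjusted p = 0.0974), with library size only (0.185) and on FPKM values (limma, 0.43 to 0.496). GSDMD, the gasdermin cleaved by inflammatory caspases, averaged 2.67 estimated counts per library and was below the filter, as were NLRP3 and AIM2. NRF2 targets went both ways, with 11 of 31 up and 16 down (adjusted p = 0.458). TXNRD1 (-0.62), SRXN1 (-1.09) and GCLM (-0.70), which serve thioredoxin and glutathione, fell. Iron handling genes also split, with 9 of 25 up and 12 down (adjusted p = 0.607): PCBP2, an iron chaperone, rose by 0.55 and STEAP3, a ferrireductase, fell by 1.08.

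Over all genes, 9465 of 12718 were called in deficient cells, 4705 up and 4760 down (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), of which 1838 changed by at least 1 on the log2 scale. The share of calls that were up depends on the scaling: 49.7% here and 54.8% with library size only. The deepest falls among abundant genes were those of IGFN1 (log2 -3.10), ZNF526 (-2.75), LENG8 (-2.73), JRK (-2.54), ZNF469 (-2.54), ANKRD36 (-2.46, of a family with close copies) and CCDC9B (-2.43), beside HSPA8. Adjusted over the list alone, the counts of rising and falling members were equal to those over all genes for each list above except cholesterol biosynthesis, with 20 down.

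In LKB1-intact cells ARC, FOS and EGR1 rose as well. ARC rose from 0.297 ± 0.182 to 52.2 ± 5.38 CPM, FOS from 1.71 ± 0.451 to 87.6 ± 3.79 CPM and EGR1 from 0.742 ± 0.210 to 17.5 ± 1.49 CPM (SD, n = 3 each). NR4A2 rose 16.8-fold, FOSB 11.3-fold, ABCG1 11.7-fold, PTGS2 6.75-fold and SNAI1, a repressor of E-cadherin, by 3.46 on the log2 scale. The immediate early list had 16 of 23 up and 7 down (camera adjusted p = 0.00468, and adjusted p = 0.171 with an estimated correlation). The integrated stress response did not pass in intact cells (adjusted p = 0.821), with 14 of 32 up and 12 down. The median of its members was -0.04 and their mean 0.00. PPP1R15A rose by 1.43 on the log2 scale, while the amino acid transporters SLC7A1, SLC7A11 and SLC7A5 fell by 1.07, 0.99 and 0.73.

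Several metabolic lists rose in intact cells. Glycolysis had 19 of 20 members up and none down (median log2 0.34, camera adjusted p = 4.78e-06, and adjusted p = 0.171 with an estimated correlation), with GAPDH at 6790 ± 98.6 CPM against 4379 ± 31.6 CPM (SD, n = 3). Targets of hypoxia-inducible factor had 18 of 24 up and 1 down (adjusted p = 0.000229, and adjusted p = 0.171 with an estimated correlation), among them ADM (log2 1.80), NDRG1 (1.53) and BNIP3 (0.88). Ribosomal protein genes rose in 45 of 45 cases (median 0.69, adjusted p = 2.52e-15, and adjusted p = 0.208 with an estimated correlation) and nuclear oxidative phosphorylation genes in 37 of 38 (median 0.42, adjusted p = 3.02e-09, and adjusted p = 0.171 with an estimated correlation). Removing the trend with transcript length lowered these medians to 0.42 and 0.21. In neither genotype was this trend removed from the AA effect of any other list. Antioxidant enzymes had 14 of 25 up and 5 down (adjusted p = 0.0253, and adjusted p = 0.342 with an estimated correlation), with PRDX1 (0.47) and PRDX2 (0.58) up and TXNRD1 (-0.82) and SOD2 (-1.06) down. Heat shock genes had 14 of 19 up and 4 down (adjusted p = 0.0437, and adjusted p = 0.299 with an estimated correlation), with HSPB1 (0.87) and DNAJB1 (0.44) up and HSPA8 (-0.30) down. This call was lost without intact PBS replicate 2 (adjusted p = 0.0538) or intact AA replicate 3 (adjusted p = 0.0532), and with no low-count filter (adjusted p = 0.0598).

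Interferon-stimulated genes rose in intact cells, 19 of 24 with 1 down (camera adjusted p = 0.000175, and adjusted p = 0.153 with an estimated correlation). ISG15, a ubiquitin-like modifier, went from 15.7 ± 0.492 to 49.8 ± 2.16 CPM (SD, n = 3), IFIT1 rose 4.03-fold and OASL 12.1-fold. Cytosolic DNA sensing had 6 of 7 up (adjusted p = 0.0229, and adjusted p = 0.171 with an estimated correlation), including IFI16 (0.75) and STING1 (0.50). This list, like those of hypoxia-inducible factor targets, antioxidant enzymes and ribosome biogenesis, was not called in deficient cells. None of them was called for the difference in AA effect either, so these calls do not show a response confined to intact cells. NF-kB targets fell, 12 of 20 with 4 up (adjusted p = 0.0221, and adjusted p = 0.239 with an estimated correlation): NFKB2 by 1.31, BIRC3 by 1.51 and the feedback inhibitor TNFAIP3 by 1.99 on the log2 scale. Mitochondrial genome transcripts fell in 13 of 13 cases (median -0.78, adjusted p = 4.78e-06, and adjusted p = 0.208 with an estimated correlation), with MT-ND6 at -2.49. Cholesterol biosynthesis fell in 18 of 24 with 2 up (adjusted p = 0.000571, and adjusted p = 0.171 with an estimated correlation), with SQLE at -0.86. Ribosome biogenesis genes fell in 15 of 25 with 3 up (adjusted p = 0.0158, and adjusted p = 0.171 with an estimated correlation), among them RRP12 (-0.62) and RRS1 (-0.92). G2 and M phase genes had 19 of 30 up and 5 down (adjusted p = 0.00792, and adjusted p = 0.171 with an estimated correlation), with HMMR up by 0.84 and MKI67 down by 0.62.

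The pyroptosis list did not pass in intact cells either (camera adjusted p = 0.371), with 6 of 17 up and 2 down. CASP4, CASP1, IL18 and TXNIP rose 1.25-fold, 1.57-fold, 1.36-fold and 1.22-fold, and GSDME had a log2 change of -0.01 (SE 0.0376, adjusted p = 0.791). NRF2 targets had 16 of 31 up and 9 down (adjusted p = 0.358), with AKR1C3 up by 1.11 and SLC7A11 down. Iron handling had 10 of 25 up and 9 down (adjusted p = 0.821), with the ferritin light chain FTL up by 0.50 and the mitochondrial iron importer SLC25A37 down by 0.92. CREB-CRTC targets did not pass (adjusted p = 0.094), with 10 of 20 up and 5 down, among them CPS1, up by 0.50. In total 8872 genes were called, 4392 up and 4480 down, of which 1287 changed by at least 1 on the log2 scale. The share up was 49.5% here and 56.2% with upper quartile factors. The deepest falls among abundant genes were CDC42EP2 (log2 -3.52), IGFN1 (-2.86), ZNF469 (-2.85), RELB (-2.43), LENG8 (-2.41), MARS2 (-2.26) and CCDC9B (-2.23), beside MT-ND6. Adjusted over the list alone, the member counts of the lists above were equal except for oxidative phosphorylation, with 38 up, and cholesterol biosynthesis, with 3 up.

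The AA effects of the genotypes were then set against each other. Across the 12718 genes the log2 fold changes had a Pearson correlation of 0.745 and a Spearman correlation of 0.734; genes are not independent replicates, and the comparisons share no library. Calls overlapped in 3127 rising genes, where independent lists would share 1625, and in 3440 falling genes, where they would share 1677. Another 751 genes were called in both genotypes in opposite directions.

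**Figure D2:**
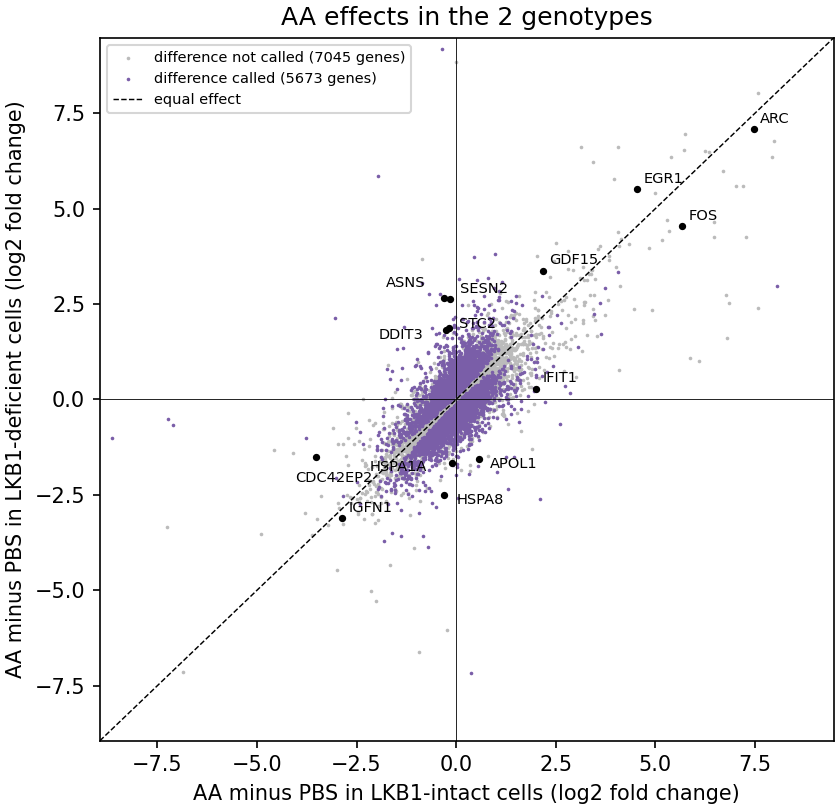
Log2 fold change of AA over PBS in LKB1-intact (x axis) and LKB1-deficient cells (y axis) for the 12718 tested genes. Purple points are the 5673 genes whose effects differed between the genotypes (adjusted p under 0.05), grey points the others, black points named genes, and the dashed line marks equal effects; ASNS and SESN2 lie above it and HSPA8 and APOL1 below.

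A direct test of the difference in AA effect between deficient and intact cells also separated the integrated stress response. This test and the comparison of genotypes under AA below reuse the libraries of the comparisons above, so they are not independent of them. Of 32 members, 30 had a higher AA effect in deficient cells and 1 a lower one (median difference 1.11 log2, camera adjusted p = 1.07e-20, and adjusted p = 0.000138 with an estimated correlation). ASNS stood at 366.5 ± 8.07 CPM in deficient against 47.3 ± 4.52 CPM in intact cells under AA (SD, n = 3; difference 2.97 log2, SE 0.0827). SESN2, a leucine sensor that inhibits mTORC1, rose to 40.8 ± 2.44 against 6.32 ± 0.149 CPM, and DDIT3, the CHOP transcription factor, to 31.9 ± 0.829 against 7.16 ± 0.926 CPM (SD, n = 3). STC2, AARS1 and PSAT1 differed by 2.06, 1.40 and 1.46 log2. Heat shock genes differed the other way, with 16 of 19 lower and none higher (median -0.73, adjusted p = 3.15e-11, and adjusted p = 0.0202 with an estimated correlation). HSPA8 differed by -2.22, HSPA1A by -1.56, HSP90AA1 by -1.08 and HSP90AB1 by -0.73 log2. These 2 were the lists whose call held with an estimated correlation.

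**Figure D3:**
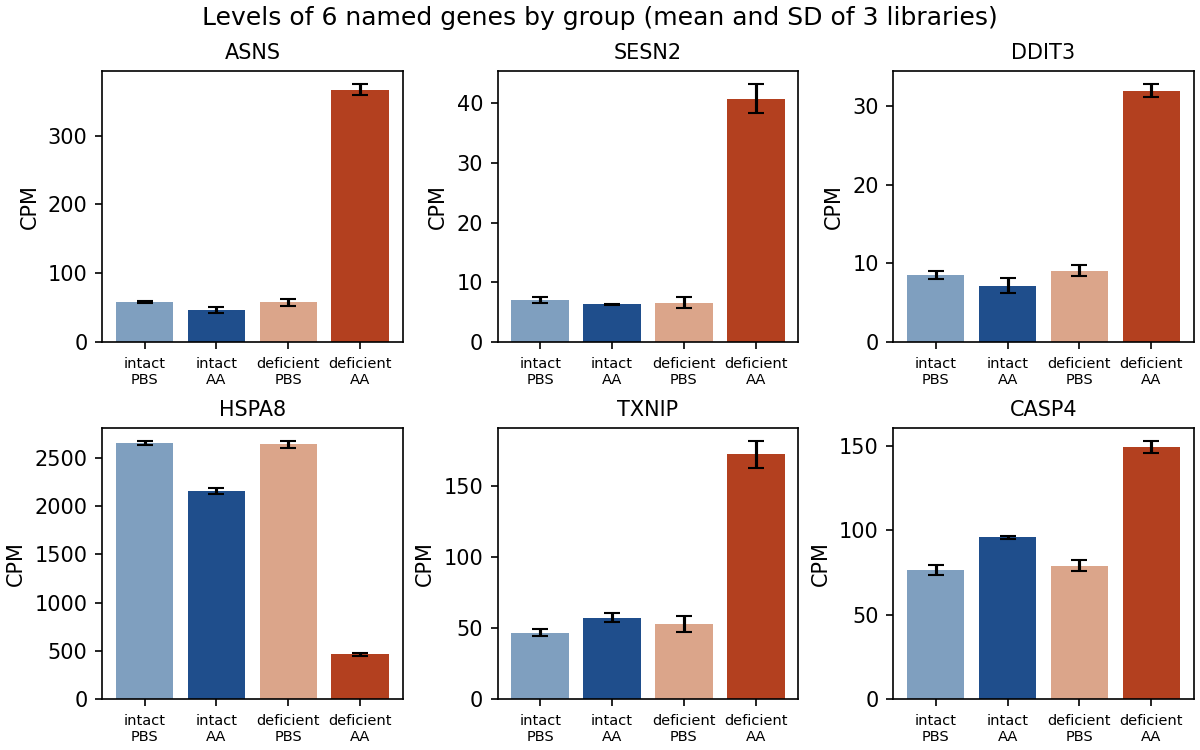
Mean level in CPM of 6 named genes in the 4 groups, with bars of 1 SD over 3 libraries, on axes that start at 0. ASNS, SESN2 and DDIT3 were highest and HSPA8 lowest in LKB1-deficient cells under AA (366.5, 40.8, 31.9 and 461.6 CPM).

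NF-kB targets were higher in their AA effect in deficient cells, 15 of 20 with 1 lower (median difference 0.80 log2, camera adjusted p = 9.54e-06, and adjusted p = 0.0899 with an estimated correlation), with NFKB2 at 1.10 and RELB at 1.57. As a list they fell under AA in intact cells (median log2 -1) and were not called in deficient cells. A higher effect here therefore does not by itself mean a rise. Glycolysis was lower in 16 of 20 with 1 higher (median -0.38, adjusted p = 9.54e-06, and adjusted p = 0.201 with an estimated correlation), including PGAM1 (-0.78) and PKM (-0.52). Mitochondrial genome transcripts were lower in 11 of 13 with 1 higher (adjusted p = 0.00021, and adjusted p = 0.302 with an estimated correlation), for example MT-CO1 (-0.65). Cholesterol biosynthesis was lower in 14 of 24 with 1 higher (adjusted p = 0.00341, and adjusted p = 0.109 with an estimated correlation), with HMGCS1 at -1.12. NRF2 targets were lower in 17 of 31 with 4 higher (adjusted p = 0.00864, and adjusted p = 0.0899 with an estimated correlation), PRDX1 by 0.74 and AKR1C3 by 0.94 log2, while SLC7A11, the cystine transporter, which is also on the stress response list, was higher by 1.25. Interferon-stimulated genes were lower in 10 of 24 with 1 higher (adjusted p = 0.0118, and adjusted p = 0.123 with an estimated correlation), with IFIT1 at -1.73 and a median of -0.41 that ranged from -0.43 to -0.20 over 6 other scalings. Ribosomal protein genes were lower in 18 of 45 (adjusted p = 0.0105, and adjusted p = 0.651 with an estimated correlation), with RPL4 at -0.43 and the call lost without intact AA replicate 3 (adjusted p = 0.0762), and histone genes higher in 3 of 10 (adjusted p = 0.0128, and adjusted p = 0.109 with an estimated correlation), with H2AC6 at 1.63.

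The pyroptosis list did not pass the test of the difference (camera adjusted p = 0.194). Of its 17 members, 6 had a higher AA effect in deficient cells: TXNIP by 1.42 log2 (SE 0.0891, adjusted p = 3.42e-11), IL1A by 1.72, IL18 by 0.60, CASP4 by 0.59, NINJ1 by 0.39 and GSDME by 0.32. The IL1A value was the least precise of the 6 (SE 0.476, edgeR adjusted p = 0.00544). CASP1 (-0.38) and DPP9 (-0.37) had a lower one. The CASP1 call was lost with DESeq2 (adjusted p = 0.0655), library size only (0.0637) or no low-count filter (0.0561), and without any of intact PBS replicate 2 (0.0952), intact AA replicate 2 (0.0588), deficient PBS replicate 1 (0.0562) or deficient AA replicate 2 (0.0746). TXNIP reached 172 ± 9.41 CPM and CASP4 149.5 ± 3.45 CPM in deficient cells under AA, against 57.1 ± 3.13 and 95.8 ± 1.08 CPM in intact cells (SD, n = 3). Iron handling (adjusted p = 0.297; 5 of 25 higher, 8 lower) and CREB-CRTC targets (adjusted p = 0.9; 5 of 20 higher, 5 lower) did not pass. STEAP3 differed by -1.17 log2, and the EGF receptor ligand AREG by 1.94.

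**Figure D4:**
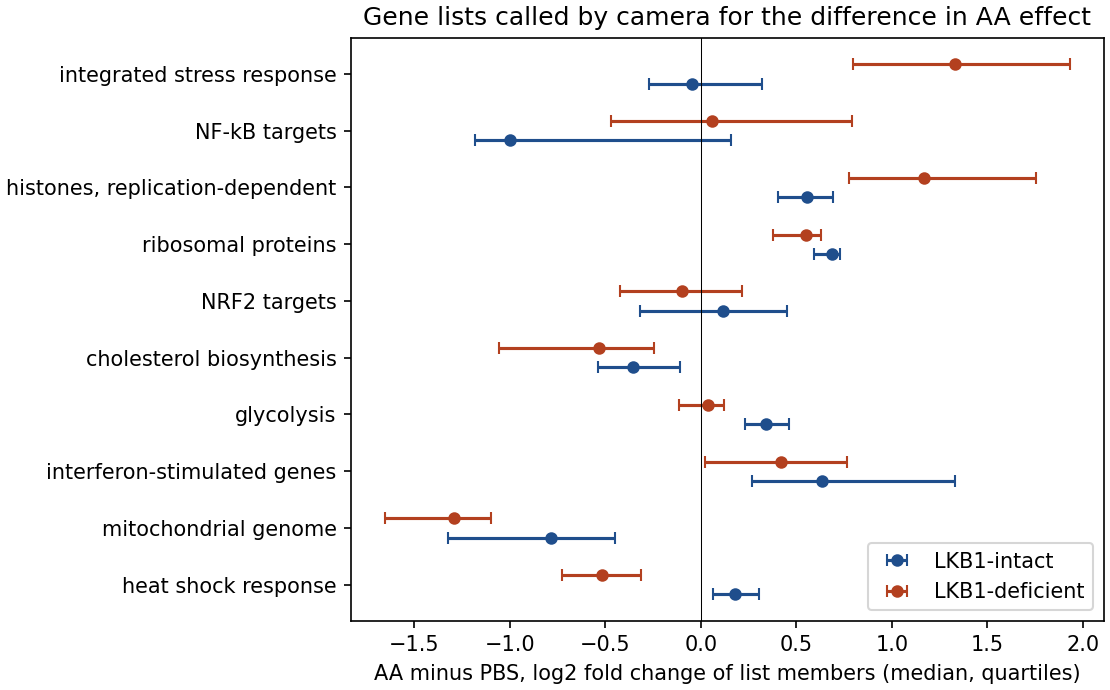
Log2 fold change of AA over PBS of the members of the 10 lists that camera called for the difference in AA effect between the genotypes, in LKB1-intact (blue) and LKB1-deficient cells (red). With an estimated correlation, the calls of the integrated stress response and heat shock lists held and the others were lost (adjusted p = 0.0899 to 0.651 with an estimated correlation). Points are medians and bars run from the lower to the upper quartile of members; the integrated stress response medians were -0.04 and 1.33 and the heat shock medians 0.18 and -0.52.

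The difference in AA effect was called for 5673 genes, 2747 higher and 2926 lower in deficient cells, of which 450 differed by at least 1 log2. The share higher was 48.4%, and on the same counts 57.9% with library size only and 44.6% with upper quartile factors. It was 60.3% of 4457 calls on the deposited FPKM values with a pseudocount of 1. Which direction holds the majority thus depends on the scaling. Genes outside the lists called for this difference were ranked if their mean log2 CPM was at least 3. The largest positive differences were SERPINE2 (2.17), IGFBP1 (2.15), CLDN1 (2.03) and CDC42EP2 (2.01). The largest negative ones, RGPD5 aside, were APOL1 (-2.15), FBXO9 (-1.80), TMEM47 (-1.60) and NES (-1.56). RGPD5 (-2.98, adjusted p = 0.0273) belongs to a family of near-identical copies and its replicates scattered widely (18.1 ± 11.1 CPM in deficient cells under PBS, SD, n = 3), so it is uncertain; DESeq2 gave an adjusted p = 0.159. Adjusted over the list alone, the counts above were equal except for NRF2 targets, with 19 lower, and iron handling, with 10 lower.

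Without AA the genotypes were close. Under PBS, 35 of 12718 genes differed, 7 higher and 28 lower in deficient cells, with STK11 the largest fall. Genes of the extracellular matrix and the mesenchymal state were lower as a list (28 tested, 3 lower and none higher, and 12 lower when adjusted over the list alone; median log2 -0.12, camera adjusted p = 3.89e-06, and adjusted p = 0.182 with an estimated correlation). COL5A2, a fibrillar collagen chain, was at 1.98 ± 0.0450 against 4.42 ± 0.321 CPM (SD, n = 3), and the fibronectin gene FN1 was lower by 0.34 log2. CALD1, an actin-binding caldesmon, was lower by 0.40 (adjusted p = 0.000173) and SCIN, which severs actin, by 0.35, and LAMA4, MYO5A, NFATC2, F2RL2 and RNF31 by 0.67, 0.63, 0.62, 0.53 and 0.53 log2. GDF15 (0.49), DSE (0.41), PDZD2 (0.35), IGFBP7 (0.24), CYP1B1 (0.22), ANXA3 (0.19) and HKDC1 (0.14) were higher. S phase (adjusted p = 0.00191, and adjusted p = 0.154 with an estimated correlation), G2 and M phase (adjusted p = 0.00756, and adjusted p = 0.227 with an estimated correlation) and cholesterol biosynthesis (adjusted p = 0.029, and adjusted p = 0.3 with an estimated correlation) were higher as lists by medians of 0.04, 0.04 and 0.05, with no member called over all genes and 1, 0 and 0 adjusted over the list alone. The cholesterol call was lost with fry (adjusted p = 0.0704) and without intact PBS replicate 1 (0.0522) or 3 (0.0889) or deficient PBS replicate 1 (0.0837) or 2 (0.202). Members not called had log2 differences of 0.01 (RRM1), 0.02 (MCM7), 0.03 (MKI67), 0.07 (TOP2A) and 0.09 (HMGCS1). The count of 35 rested on few libraries: it was 6 without either intact PBS replicate 2 or deficient PBS replicate 1, 9 without intact PBS replicate 1, and 15 and 14 without intact or deficient PBS replicate 3. Of the genes named under PBS, STK11 and CALD1 kept their call under each alternative run on single genes, SCIN lost it on FPKM values, and the others lost it without intact PBS replicate 2. FN1 (adjusted p = 0.0449) lost it without any single library but intact AA replicate 3 (adjusted p = 0.0502 to 0.285). On FPKM values the count was 5, of which 40% were higher, against 20% of the 35.

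Under AA, 7501 genes differed between the genotypes, 3653 higher and 3848 lower in deficient cells. The share higher was 48.7%, and on the same counts 57.5% with library size only and 45.1% with upper quartile factors. It was 60.3% of 6193 calls on FPKM values with a pseudocount of 1. The integrated stress response was higher in 30 of 32 members with 1 lower (median 1.13 log2, camera adjusted p = 5.04e-18, and adjusted p = 0.000232 with an estimated correlation), ASNS 7.76-fold and SESN2 6.44-fold, and ETV5, STC2, CLDN1 and CDC42EP2 were higher by 2.32, 2.19, 2.13 and 2.09 log2. Heat shock genes were lower in 17 of 19 (adjusted p = 2.12e-09, and adjusted p = 0.0351 with an estimated correlation), HSPA8 4.68-fold. APOL1 was 4.61-fold and OLFML1 3.22-fold lower. NF-kB targets were higher in 17 of 20 with 2 lower (adjusted p = 9.63e-06, and adjusted p = 0.0899 with an estimated correlation), with IL6 2.13-fold higher, and histones in 8 of 10 (adjusted p = 0.00466, and adjusted p = 0.0899 with an estimated correlation). Glycolysis was lower in 18 of 20 with 1 higher (adjusted p = 6.31e-06, and adjusted p = 0.175 with an estimated correlation), with LDHA at -0.41. The mitochondrial genome was lower in 11 of 13 with 1 higher (adjusted p = 0.000871, and adjusted p = 0.347 with an estimated correlation) and cholesterol biosynthesis in 14 of 24 with 3 higher (adjusted p = 0.0188, and adjusted p = 0.175 with an estimated correlation). NRF2 targets were lower in 19 of 31 with 5 higher (adjusted p = 0.0192, and adjusted p = 0.114 with an estimated correlation) and interferon-stimulated genes in 13 of 24 with 3 higher (adjusted p = 0.0192, and adjusted p = 0.175 with an estimated correlation). Ribosomal proteins were lower in 20 of 45 with 1 higher (median -0.08, and -0.10 to -0.02 over 6 other scalings; adjusted p = 0.0367, and adjusted p = 0.691 with an estimated correlation), a call lost without intact AA replicate 3 (adjusted p = 0.211) or deficient AA replicate 1 (0.0697) or 3 (0.104). G2 and M phase genes were higher in 19 of 30 with 5 lower (adjusted p = 0.0192, and adjusted p = 0.175 with an estimated correlation), with TPX2 at 0.40 and KIF20A at -0.95. Adjusted over the list alone, counts differed for cholesterol biosynthesis (4 higher), interferon-stimulated genes (4 higher, 14 lower), G2 and M phase (20 higher) and ribosomal proteins (19 lower).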

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

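The tests of the handling of 1 group, of a mislabelled PBS library, of a few abundant genes and of library depth, and the account of which splits gave many genes, were chosen after the results were seen. The test of the difference itself singled out 5673 genes whose AA effect differed between LKB1-deficient and LKB1-intact cells (edgeR quasi-likelihood test, adjusted p under 0.05). Camera called 10 lists for this difference; the integrated stress response and heat shock calls held with an estimated correlation and the others were lost (adjusted p = 0.0899 to 0.651 with an estimated correlation). Their median differences, deficient minus intact, were 1.11 for the integrated stress response, -0.73 for heat shock, 0.80 for NF-kB targets, -0.54 for the mitochondrial genome, -0.41 for interferon-stimulated genes (-0.43 to -0.20 over 6 other scalings), -0.38 for glycolysis, -0.21 for cholesterol biosynthesis, -0.20 for NRF2 targets, -0.12 for ribosomal proteins (-0.15 to -0.07) and 0.62 for histones. Among the 100 named genes with such a difference, the effect was lower in deficient cells for RGPD5 (-2.98), HSPA8 (-2.22), APOL1 (-2.15), FBXO9 (-1.80), IFIT1 (-1.73), TMEM47 (-1.60), NES (-1.56), HSPA1A (-1.56), OLFML1 (-1.52), SNAI1 (-1.22), NDRG1 (-1.22), STEAP3 (-1.17), FOS (-1.14), HMGCS1 (-1.12), HSP90AA1 (-1.08), OASL (-1.06), KIF20A (-1.04), ZNF526 (-1.03), F2RL2 (-0.95), AKR1C3 (-0.94), ANKRD36 (-0.91), SQLE (-0.81), PGAM1 (-0.78), PRDX1 (-0.74), MT-CYB (-0.74), HSP90AB1 (-0.73), NR4A2 (-0.72), JRK (-0.66), MT-CO1 (-0.65), CALD1 (-0.61), DSE (-0.54), PKM (-0.52), HSPB1 (-0.51), FN1 (-0.46), LDHA (-0.45), RPL4 (-0.43), BNIP3 (-0.38), DNAJB1 (-0.38), CASP1 (-0.38), DPP9 (-0.37), LENG8 (-0.32), PRDX2 (-0.31), PDZD2 (-0.29), ID1 (-0.25), MCM7 (-0.22), MT-ND5 (-0.22), FTL (-0.22), MKI67 (-0.22), SCIN (-0.19), GCLM (-0.19), GAPDH (-0.14) and RRM1 (-0.09). It was higher for IFI16 (0.20), TXNRD1 (0.21), SDHB (0.22), SOD2 (0.22), PCBP2 (0.31), ZNF469 (0.31), GSDME (0.32), SLC25A37 (0.33), MT-ND6 (0.33), TPX2 (0.36), HKDC1 (0.37), NINJ1 (0.39), HMMR (0.40), RRP12 (0.44), SLC7A5 (0.45), ANXA3 (0.46), RNF31 (0.49), CASP4 (0.59), IL18 (0.60), SLC7A1 (0.61), TNFAIP3 (0.68), PPP1R15A (0.70), BIRC3 (0.78), LAMA4 (0.91), EGR1 (0.97), NFATC2 (0.98), CYP1B1 (1.04), NFKB2 (1.10), IL6 (1.13), GDF15 (1.2), SLC7A11 (1.25), SARS1 (1.36), AARS1 (1.40), TXNIP (1.42), PSAT1 (1.46), RELB (1.57), H2AC6 (1.63), IL1A (1.72), AREG (1.94), ETV5 (1.96), CDC42EP2 (2.01), CLDN1 (2.03), STC2 (2.06), DDIT3 (2.07), IGFBP1 (2.15), SERPINE2 (2.17), SESN2 (2.78) and ASNS (2.97).

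Other splits of the libraries bear on the counts. For the difference in AA effect, 100 of 200 possible splits of genotype within treatment were drawn, the real one included. Of these, 6 gave as many genes as the real 5673, with 5998 the highest of the others. The other 5 were among 8 drawn splits that kept the AA libraries of the genotypes apart (5608 to 5998 genes). Such splits keep the AA contrast, up to its sign, and regroup PBS libraries, where only 35 genes differed. They nearly repeat the real split, so this count cannot judge chance and does not exclude it. The 91 splits that mixed the AA libraries called at most 1 gene. This points to a structure of the AA libraries by genotype. The 10 splits of each comparison of 3 with 3 libraries are too few for a share under 0.05; 1 of 10, the real one, gave as many genes each time, with 9465, 8872, 35 and 7501 genes against highest others of 2, 0, 3 and 0 for AA in deficient cells, AA in intact cells, genotype under PBS and genotype under AA.

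Ribosomal protein and nuclear oxidative phosphorylation genes rose under AA in both genotypes by camera, calls lost with an estimated correlation (adjusted p = 0.391 and 0.396 in deficient and 0.208 and 0.171 in intact cells with an estimated correlation). A trend with GC content as the whole source is argued against, since 96.8% of their median was kept without it, and so is the weight of a few abundant genes, since the share of counts that the 50 most abundant genes, members of these lists aside, gave up could lift the others by at most 9.16% of that median in any pair of an AA and a PBS library. Transcript length stays open: removing its trend kept 31.3% of the median in deficient cells (0.44 to 0.14) and 55% in intact cells (0.60 to 0.33). In deficient cells the oxidative phosphorylation call ended because its median went from 0.34 (quartiles 0.17 and 0.46) to 0.06 (quartiles -0.06 and 0.18), while the ribosomal protein median there went from 0.55 (quartiles 0.38 and 0.63) to 0.19 (quartiles 0.07 and 0.43) and stayed called (adjusted p = 0.00127, and 2.54e-11 in intact cells). The effect of AA itself on these short transcripts also stays open.

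The integrated stress response differed between genotypes. Transcript length and GC content are argued against, with 100% of the median difference kept without their trend, whose SD over genes was 0.0663 log2. Library depth as the whole source is argued against too: the most extreme totals of the groups would shift even unscaled counts by 0.36 log2, 32.3% of the median difference. Handling of 1 group of cultures cannot be told apart from genotype and treatment, because each group is 1 condition and the spread between its libraries (coefficient of variation 0.0385) says nothing about it. A dependence of the response on LKB1 is the biological explanation the design names, and it stays open.

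Many genes differed between genotypes under AA and few under PBS. The ratio of median standard errors, 1.02, cannot judge a lower precision under PBS, because 1 fit gave the 4 groups a shared spread. The chi-square per degree of freedom between replicates of intact cells ran from 1.99 to 2.37 under PBS and from 2.69 to 4.46 under AA. In deficient cells it ran from 3.24 to 4.06 under PBS and from 2.44 to 3.11 under AA. By that measure the scatter under PBS was wider in deficient and narrower in intact cells. A lower precision under PBS thus stays open for deficient cells. A mislabelled PBS library is argued against by STK11, whose highest deficient value was 27.8% of the lowest intact one. A genotype difference that AA brings out is the biological explanation the design names, and handling of the AA cultures stays open beside it.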

How the results depend on the processing

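No alternative was added after the data were seen. None of the called values of named genes and none of the 49 called list tests changed direction under the alternatives run on them. Over 6 other scalings, medians of called lists fixed beforehand that moved by over 1.5 times were those of the difference in AA effect for interferon-stimulated genes (-0.41, range -0.43 to -0.20) and ribosomal proteins (-0.12, range -0.15 to -0.07), and of the genotypes under AA for NRF2 targets (-0.22, range -0.24 to -0.11) and ribosomal proteins (-0.08, range -0.10 to -0.02). Of the called lists chosen after the data were seen, those of ZNF genes under AA in both genotypes (-0.62, range -0.61 to -0.41, and -0.58, range -0.57 to -0.37) and of mitochondrial ribosomal proteins for the difference (0.12, range 0.09 to 0.18) moved as much. The counts of called genes under AA in each genotype, for the difference and for the genotypes under AA stayed within 1.5 times except with a log2 change of at least 1 required, which left 1838, 1287, 450 and 590 genes. Under PBS, 35 genes became 54 with DESeq2, 111 with no low-count filter, 5 on FPKM with either pseudocount, 4 on FPKM with no filter, 5 at an adjusted p under 0.01 and 6 with a log2 change of at least 1; the cause was not tested. Called lists went from 49 to 5 with an estimated correlation and to 134 with fry, which asks another question and shared 48. The correlation of AA effects was 0.49 with no filter, 0.7545 with a stricter filter and 0.7591 over called genes, settings that change which genes enter. Leaving out 1 library gave 9083 to 9514 genes for AA in deficient cells, 8332 to 8979 in intact cells, 5242 to 5532 for the difference, 6 to 43 under PBS and 6876 to 7580 under AA, an STK11 difference of -2.18 to -1.97 log2, 47 to 53 lists and correlations of 0.7025 to 0.726. These correlations all lay below the 0.745 of all 12 libraries. The filter by group was run anew on the libraries left, which can also change which genes enter. Under PBS the count of genes was 9, 6 and 15 without intact PBS replicates 1, 2 and 3, and 6 and 14 without deficient PBS replicates 1 and 3. Of 2628 gene values with a library left out, 95 lost their call. Replicate numbers are shared by the groups but do not pair the libraries: deviations of same-numbered libraries correlated at -0.0939 to 0.0537 over 18 pairs, and 1 of 12 libraries correlated best with its own number. With the replicate number as a block, the counts were 9402, 8776, 5554, 32 and 7402, with 49 lists, an STK11 difference of -2.08 and a correlation of 0.7455; the PBS calls of FN1 (adjusted p = 0.0627) and HKDC1 (0.0617) were lost, and the other called values of named genes and lists kept their call. At this depth, with 16055534 to 20306129 counts per library, genes such as GSDMD, with a mean count of 2.67, could not be tested.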

Other observations

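The lists and tests in this part were chosen after the data were seen, some after members had stood out, and are descriptions rather than independent evidence, except the lists of markers of other cell types, whose named members were chosen after their values were seen. MAPK phosphatase, Sprouty and ETS genes, which respond to ERK signalling, rose in deficient cells under AA in 10 of 11 cases with none down (median log2 1.96, camera adjusted p = 9.66e-05, and adjusted p = 0.096 with an estimated correlation). In intact cells 9 rose and 2 fell (median 0.76, adjusted p = 0.00828, and adjusted p = 0.137 with an estimated correlation), and 8 had a higher effect in deficient cells (adjusted p = 2.8e-05, and adjusted p = 0.0672 with an estimated correlation). Amino acid carriers parted: in deficient cells 9 of 12 rose and 3 fell (adjusted p = 0.0264, and adjusted p = 0.133 with an estimated correlation), and in intact cells 2 rose and 8 fell (adjusted p = 0.0252, and adjusted p = 0.137 with an estimated correlation). For the difference 10 were higher and 2 lower (adjusted p = 1.42e-05, and adjusted p = 0.0273 with an estimated correlation). SLC7A1, SLC7A5 and SLC7A11 are among the members this list shares with the integrated stress response list, so this repeats part of that result. Cytosolic aminoacyl-tRNA synthetases rose in 16 of 20 cases with 3 down in deficient cells (adjusted p = 8.19e-06, and adjusted p = 0.12 with an estimated correlation). In intact cells they did not pass (adjusted p = 0.0728, 9 up and 2 down), and for the difference 15 were higher and 3 lower (adjusted p = 2.33e-06, and adjusted p = 0.0867 with an estimated correlation). This list too shares members with the integrated stress response list, AARS1 and SARS1 among them. Their mitochondrial counterparts did not pass in deficient cells (adjusted p = 0.496, 6 of 17 up and 8 down) or in intact cells (adjusted p = 0.597, 6 up and 4 down), where their median was 0.04 and -0.01 at its lowest, on FPKM values. Proteasome subunits rose in 33 of 37 cases with 1 down in intact cells (adjusted p = 1.55e-08, and adjusted p = 0.0464 with an estimated correlation) and in 23 with 9 down in deficient cells (adjusted p = 0.0315, and adjusted p = 0.329 with an estimated correlation). They were lower in their effect in deficient cells in 20 with 6 higher (adjusted p = 0.00572, and adjusted p = 0.276 with an estimated correlation). Mitochondrial ribosomal proteins rose in 56 of 77 cases with 9 down in deficient cells (adjusted p = 8.19e-06, and adjusted p = 0.138 with an estimated correlation) and in 55 with 3 down in intact cells (adjusted p = 5.52e-06, and adjusted p = 0.137 with an estimated correlation), and for the difference 30 were higher and 10 lower (adjusted p = 0.0424, and adjusted p = 0.507 with an estimated correlation). The trend with transcript length was not removed for this list or for proteasome subunits. The CCT chaperonin did not pass in deficient cells (adjusted p = 0.386, 4 of 8 up and 2 down) and rose in 7 of 8 in intact cells (adjusted p = 0.016, and adjusted p = 0.164 with an estimated correlation).

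Genes named ZNF, mostly zinc finger transcription factors, fell under AA in 251 of 385 cases in deficient cells (53 up, median -0.62, camera adjusted p = 1.34e-07, and adjusted p = 0.0928 with an estimated correlation) and in 247 in intact cells (34 up, median -0.58, adjusted p = 7.72e-10, and adjusted p = 0.0458 with an estimated correlation). This list was chosen after some of its members were seen among the deepest falls, so whether such genes fell more than others of like length and abundance stays open. As a description of these libraries, among 10000 random lists matched on transcript length and mean expression, the percentile of their median was 0 in both genotypes, with lowest matched medians of -0.21 and -0.17. Over 6 other scalings the medians ranged from -0.61 to -0.41 in deficient and from -0.57 to -0.37 in intact cells.

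Of the markers of other cell types, 4 of 12 fibroblast, 1 of 16 leukocyte and 2 of 10 endothelial genes passed the low-count filter. The highest of each list were not near the filter: FBLN1 averaged 6350 estimated counts per library, CD68 1760 and ESAM 348. In deficient cells under AA the endothelial markers ESAM and CDH5 moved apart (1.21 and -2.89 log2). Genes with a count numbered 14129 to 14366 in PBS and 14451 to 14769 in AA libraries.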
